A study of Mus musculus with 12 samples.

How the data were processed

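RNA from 12 samples of MC3T3 sc4 cells, 4 per group, was measured on an Illumina mouse BeadChip. Per the labels, cells were treated with collagenase for 40 minutes before harvest, and biotin-labelled cRNA was made from 200 ng of total RNA. The deposited table of values that were not normalized holds, per the file headers, a linear signal intensity for each probe and array. Beside each intensity the deposited table gives a detection p-value for that probe and array. The authors also deposited a table of normalized intensity values on a linear scale. They do not state its normalization, and its columns have median intensities of nearly the same size. Columns of the first table carry array numbers and group names, so arrays are named here by number. Only the columns of the second table carry replicate numbers.

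The intensities were background-corrected with the normexp model, using the detection p-values to estimate the background, after which an offset of 16 was added, and were quantile-normalized and put on the log2 scale with the neqc function of limma 3.58.1 in R 4.3.3. The offset shrinks the fold changes of dim genes. Equal RNA input and normalization would both remove a shift shared by all genes. Probes were kept when the detection p was under 0.01 on at least 4 of the 12 arrays. Of 45281 probes, 34885 carried 1 gene symbol, 18 carried several and 10378 none in the annotation at hand. Of 16431 kept probes 14136 had 1 symbol, and each gene was represented by its kept probe with the highest mean, which gave 9153 genes. The other 2295 kept probes are unnamed here, which does not mean that they match no gene.

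Linear models were fitted with limma to the 3 groups together, with moderated tests for 2 h of SAHA against DMSO, 6 h against DMSO and 6 h against 2 h. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes, and a gene was called changed at an adjusted p under 0.05. Where a gene was undetected on all arrays of a group, its fold is given as a lower bound against the detection limit, or not at all where that bound is 0. A gene detected on some arrays of a group keeps its fitted value, and named genes detected on only 1 or 2 are said so. Counts and list medians are also given with such genes at their bounds. Of 52 gene lists drawn up from textbook knowledge, 49 had at least 5 measured genes and were tested with camera at a preset correlation of 0.01, with adjustment over the lists of each comparison. Camera compares a list with all other genes. The same test with a correlation estimated from the data and the fry test were run beside it. The overlap of the time points was set beside independent lists of the same sizes, 100 simulated unchanged groups and the 6 splits of the DMSO arrays.

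The samples, comparisons, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined, apart from the tests and alternatives that are said to have been chosen after. The rule names, for each comparison, the 10 largest rises and falls by fitted value among changed genes that do not carry a predicted or clone name, were detected on all 4 arrays of a group and had groups that do not overlap, up to 4 members of each described list with the smallest p, and 30 genes fixed by name. Of these 30, 9 had no kept probe with 1 symbol, Runx2 among them, and were not analysed. Genes named outside this rule are said so where they appear. Alternatives covered background correction, normalization, the authors' normalized values, the probe filter, the probe that stands for a gene, the samples in the fit, the variance model, array weights, the threshold, each array left out in turn and the split of the controls. The call rules were tested on simulated data with 50 genes planted at each fold. At 1.5-fold 44, 48 and 47 of them were found in the 3 comparisons, and at 1.25-fold 21, 18 and 24, while at 2-fold all 50 were found. Unchanged genes gave 8, 6 and 8 false calls, and 0 of 20 random lists were called. The simulated noise was independent between genes, and few genes were changed. The check thus does not cover correlation within lists or the share of changed genes in the data. No batch, slide or date is given for the arrays.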

Results

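Gene expression was measured in MC3T3 sc4 cells, a subclone of a mouse calvarial pre-osteoblast line that differentiates in medium with ascorbic acid and beta-glycerophosphate. On day 4 of differentiation the cells were given 20 µM SAHA (vorinostat), an inhibitor of zinc-dependent histone deacetylases, or its solvent DMSO. The 12 arrays fell into 3 groups of 4, which were DMSO, SAHA for 2 h and SAHA for 6 h. The study's title names histone deacetylase inhibition, osteoblast maturation and the state of histone H4. Each array held 45281 probes, and 9153 genes were tested. Detected probes numbered 15610 to 16065 on the DMSO arrays, 14904 to 15982 after 2 h of SAHA and 15264 to 15705 after 6 h. The number of arrays limits the precision, and the median standard error of a log2 change was 0.08. Across genes, the SD of the log2 difference between a pair of arrays was 0.16 to 0.24 within groups and 0.54 to 0.89 between groups. The labels do not say whether the 4 arrays of a group came from separate cultures, so the p-values measure only the spread between these samples. They also do not give the time for which the control cells were kept in DMSO, and the treatment text names only the 2 h exposure, so time in culture cannot be separated from time in SAHA. Values after ± are standard errors of the limma fit, with n = 4 arrays in each group.

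The comparison of 2 h of SAHA with DMSO asked which transcripts differed early in the exposure. Pkp2, which encodes the desmosome protein plakophilin 2 (probe ILMN_2927565), rose 10.9-fold (log2 change 3.45 ± 0.07), and Id1, an inhibitor of basic helix-loop-helix transcription factors, rose 6.20-fold (2.63 ± 0.08). Bcl2l11, which encodes the pro-apoptotic protein Bim, rose 5.28-fold (2.40 ± 0.07). Trib3, a pseudokinase gene of the integrated stress response, fell by 3.55 ± 0.07 on the log2 scale, with changes from -2.25 to -1.80 for its other 2 probes. Kmt5b, which encodes a methyltransferase for lysine 20 of histone H4, fell by 3.04 ± 0.08, with changes from -2.71 to -1.46 for its other 3. Sp7, which encodes the osteoblast transcription factor osterix (probe ILMN_2733114), was 4.30-fold lower (-2.10 ± 0.07). Gch1, the first enzyme of tetrahydrobiopterin synthesis, was undetected in DMSO and at least 3.74-fold higher after 2 h by the probe used, while its other probe had a fitted log2 change of 0.71. The other 6 of the 10 largest rises were Dyrk3, Rbm38, Nuak2, Mknk2, Fam117a and Mcam, with log2 changes from 2.63 to 3.02. Among the 10 largest falls, Fgf7, a growth factor for epithelial cells, fell by 2.35 ± 0.07, Hexim2, an inhibitor of the elongation factor P-TEFb, fell by 2.28 ± 0.09, and Has2, a hyaluronan synthase, fell by 2.14 ± 0.10. Arhgef39 fell by 2.12 ± 0.10. Kdm8, Iba57, Trmo and Zfp551 went below detection after 2 h and were at least 6.30-fold, 3.33-fold, 3.17-fold and 1.91-fold lower. The 10 largest changes are ranked by fitted values in each comparison, and the bounds of Iba57, Trmo and Zfp551 lay under the fall of Sp7. The adjusted p of Pkp2 and of Trib3 was 6.427e-13.

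Histone genes rose at 2 h. Of the 32 measured replication-dependent histone genes, 22 rose, 0 fell and 10 did not pass, with 22 changed when adjusted over the list alone and a median log2 change of 0.49. H3c10 rose by 1.08 ± 0.06, with a log2 change of 0.71 for its other probe. H2bc14 rose by 0.91 ± 0.08, and H2ac6, undetected in DMSO, was at least 1.58-fold higher. Against the other genes the list gave an adjusted p of 5.46e-06 in camera, and adjusted p = 0.361 with an estimated correlation. Of the 18 linker and variant histone genes, 13 rose, 1 fell and 4 did not pass (14 changed when adjusted over the list alone). H1f2, a linker histone, rose by 2.38 ± 0.08 and H1f10, another one, by 1.02 ± 0.09. The median of this list was 0.57, or 0.50 with undetected members set to their bounds, at an adjusted p of 0.000182, and adjusted p = 0.218 with an estimated correlation. Genes of replication-dependent histones share sequence, so their probes are not independent. Most of their mRNAs lack a poly(A) tail, and whether the labelling measured those forms was not tested.

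Cell cycle genes of G2 and mitosis fell at 2 h. Of 22 measured, 17 fell, 0 rose and 5 did not pass (17 changed when adjusted over the list alone), with a median of -0.47. The kinase genes Plk1 and Aurka fell by 1.23 ± 0.09 and 1.09 ± 0.06, Kif2c, a mitotic kinesin, by 1.21 ± 0.06, and Cdc20, an activator of the anaphase-promoting complex, by 0.91 ± 0.06. This list had an adjusted p of 0.00015 in camera, and adjusted p = 0.146 with an estimated correlation. In the list of CDK inhibitors and quiescence genes, 10 of 13 rose, 2 fell and 1 did not pass (12 changed when adjusted over the list alone), with a median of 0.44. Foxo1, a forkhead transcription factor, rose by 1.05 ± 0.07, Tob1, an antiproliferative gene, by 0.87 ± 0.10, and Rb1, the retinoblastoma gene, by 0.61 ± 0.06, while its relative Rbl1 fell by 0.69 ± 0.07, with changes of -0.30 and -0.27 for its other 2 probes. Among genes fixed by name, Cdkn1a, which encodes the CDK inhibitor p21, had a log2 change of 0.16 ± 0.06, and its call was lost without any 1 of arrays 1, 2, 3, 5, 6 and 7 (adjusted p = 0.0545 to 0.114). Ccnd1 (cyclin D1) fell by 0.26 ± 0.06, and Myc went below detection and was at least 1.55-fold lower. The adjusted p of the list of CDK inhibitors was 0.0221, 0.0514 without normalization between arrays, and adjusted p = 0.146 with an estimated correlation. Immediate-early and AP-1 genes rose in 16 of 24 cases, fell in 4 and did not pass in 4 (20 changed when adjusted over the list alone), with a median of 0.49. Dusp5, a phosphatase of ERK, rose by 2.10 ± 0.10, and the transcription factor genes Atf3, Egr2 and Fos rose by 1.94 ± 0.13, 1.71 ± 0.08 and 1.51 ± 0.19. The list had an adjusted p of 0.0136, and adjusted p = 0.146 with an estimated correlation.

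Osteoblast transcription factor genes fell in 11 of 16 cases at 2 h, rose in 2 and did not pass in 3 (13 changed when adjusted over the list alone), with a median of -0.54. After Sp7, Alx4, a homeobox gene of skull development, fell by 1.56 ± 0.09, Zfp521, a zinc finger gene active in early osteoblasts, by 0.85 ± 0.07, and Fosl2, an AP-1 gene, by 0.71 ± 0.07. Dlx5, a homeobox gene of bone counted among the falls, was below detection after 2 h and too dim in DMSO for a fold to be given. The list had an adjusted p of 0.0133, and adjusted p = 0.146 with an estimated correlation. Of 21 osteoblast matrix and mineral genes, 16 did not pass, 1 rose and 4 fell (2 fell when adjusted over the list alone, adjusted p = 0.756 in camera). Phospho1, a phosphatase of matrix mineralization, fell by 0.44 ± 0.09. Alpl (alkaline phosphatase), Ibsp (bone sialoprotein), Bglap (osteocalcin), Col1a1 and the osteocyte gene Phex had log2 changes of -0.15 ± 0.10, 0.19 ± 0.14, 0.03 ± 0.10, 0.01 ± 0.06 and 0.27 ± 0.21 and did not pass. Homeobox patterning genes fell in 8 of 15 cases, with 0 rises and 7 that did not pass (8 changed when adjusted over the list alone). Hoxc6, Hoxa5 and Prrx1 fell by 1.38 ± 0.14, 1.08 ± 0.09 and 0.65 ± 0.07, Hoxc6 with detection on 2 of 4 arrays at 2 h. The median was -0.65, or -0.37 at the bounds, with an adjusted p of 0.0136, and adjusted p = 0.146 with an estimated correlation. With only probes detected on all 12 arrays this call was lost (adjusted p = 0.193). Of the signalling genes fixed by name, Bmp4 fell by 0.79 ± 0.05, Pik3r1, a regulatory subunit gene of PI3K, rose by 0.33 ± 0.08, and Tgfb1 had a log2 change of 0.16 ± 0.13 and did not pass.

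Genes of the acetylation machinery were also among those that changed at 2 h. Of 14 acetyltransferase and bromodomain genes, 10 fell, 2 rose and 2 did not pass (12 changed when adjusted over the list alone), with a median of -0.50. Brd8 fell by 1.31 ± 0.13, and the acetyltransferase genes Kat5 and Kat6b fell by 1.21 ± 0.09 and 1.10 ± 0.07. For this list the adjusted p was 0.0221, and adjusted p = 0.146 with an estimated correlation. Among 16 deacetylase and sirtuin genes, 6 rose, 6 fell and 4 did not pass (13 changed when adjusted over the list alone, adjusted p = 0.948 in camera). Hdac3 rose by 0.16 ± 0.05, Hdac7 fell by 0.39 ± 0.07 and Sirt1 fell by 1.26 ± 0.10. Hdac2 had a log2 change of -0.16 ± 0.06 (adjusted p = 0.0504 to 0.108 without any 1 of arrays 1, 2, 4 to 8, 11 and 12), its other probe 0.51 and the mean of its probes 0.18. None of 21 ribosomal protein genes passed (0 also when adjusted over the list alone; fry, adjusted p = 0.222), and of 13 housekeeping genes 1 rose and 1 fell (2 changed when adjusted over the list alone). Actb, Gapdh and Tbp had log2 changes of -0.04 ± 0.05, 0.10 ± 0.05 and 0.02 ± 0.06 and did not pass, but another of the 5 probes of Actb had a log2 change of 1.26.

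In all, 5360 of 9153 genes changed at 2 h in limma at an adjusted p under 0.05, of which 2549 rose and 2811 fell. At least 2-fold changes were found for 633 genes, 286 up and 347 down, or for 566 when genes undetected in a group were set to their bounds. The groups did not overlap for 53.4% of genes, against 2.86% by chance. Camera moved 8 of the 49 lists tested, and 0 with an estimated correlation, where 8 lists passed at an unadjusted p under 0.05, while fry, which does not compare a list with other genes, moved 28. As many lists as in the real grouping were moved in 2 of the 35 splits of these 8 arrays, the real one included.

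The comparison of 6 h of SAHA with DMSO asked how expression stood later in the exposure. Sp7 was 18.8-fold lower after 6 h (-4.23 ± 0.07), Prrx1, a paired homeobox gene of skeletal mesenchyme, 14.9-fold lower (-3.90 ± 0.07), and Panx3, a channel gene of osteoblasts and chondrocytes, 13.7-fold lower (-3.77 ± 0.07). Other probes of Prrx1 had log2 changes from -3.95 to -2.38. Fgf7 fell by 4.35 ± 0.07, and Ccn5, a matricellular gene, had a log2 change of -4.11 ± 0.06, Mrgprf of -4.05 ± 0.08, and Gper1, a membrane receptor gene for estrogen, of -3.89 ± 0.07. Ptprv, a tyrosine phosphatase gene of osteoblasts, and Lpin3, a phosphatidate phosphatase gene, went below detection and were at least 7.54-fold and 7.15-fold lower. Reep6, a gene of endoplasmic reticulum shaping, rose 16.5-fold (4.04 ± 0.13) and Slc9a3r1, a scaffold gene of membrane proteins, 9.82-fold (3.30 ± 0.06). Pkp2 and Fam117a rose by 3.42 ± 0.07 and 3.24 ± 0.08, and Hid1, detected on only 1 of 4 DMSO arrays, had a fitted rise of 3.51 ± 0.11. By the probes used, Gch1 was at least 21.3-fold higher and Mlf1 at least 8.81-fold, while their other probes had fitted log2 changes of 2.61 and 2.00. Itpka was at least 8.13-fold higher, H2ac6 at least 4.90-fold and Hap1 at least 4.86-fold. The largest fall by size, that of Ackr4 (-5.13 ± 0.06), depended on the probe, since 3 of its probes fell and the only 1 detected on all 12 arrays had a log2 change of 1.56. The adjusted p of Sp7 was 4.211e-14.

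**Figure D1:**
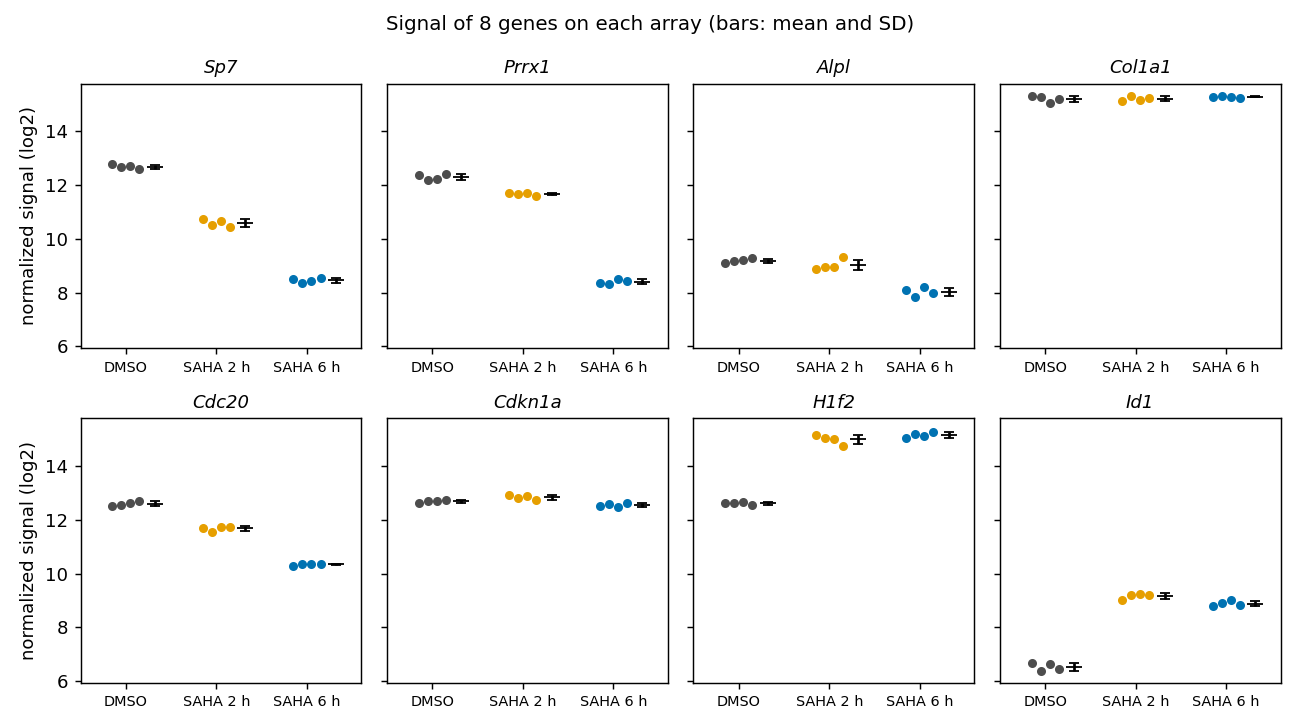
Normalized log2 signal of 8 genes on each of the 12 arrays (points), by group on the horizontal axis, with the mean and SD of each group (n = 4) beside the points. Sp7, Prrx1 and Cdc20 stepped down from DMSO through 2 h to 6 h, H1f2 and Id1 stood higher at both times, and Col1a1 had log2 changes of 0.01 at 2 h and 0.07 at 6 h.

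Of the 16 osteoblast transcription factor genes, 11 fell, 2 rose and 3 did not pass at 6 h (13 changed when adjusted over the list alone), with a median of -0.77, or -0.58 at the bounds. Alx4, Zfp521 and Dlx3 fell by 2.89 ± 0.09, 2.09 ± 0.07 and 1.51 ± 0.08, Dlx3 with detection on 1 of 4 arrays at 6 h, and Dlx5, again counted, was below detection. The list had an adjusted p of 0.0283, and adjusted p = 0.21 with an estimated correlation. Osteoblast matrix and mineral genes fell in 13 of 21 cases, with 0 rises and 8 that did not pass (13 changed when adjusted over the list alone), and a median of -0.30. Omd (osteomodulin) fell by 1.78 ± 0.13, Alpl by 1.15 ± 0.10, Tnn (tenascin-N) by 1.11 ± 0.08 and Ogn (osteoglycin) by 1.02 ± 0.07. Ibsp, Bglap, Col1a1 and Phex had log2 changes of 0.08 ± 0.14, -0.17 ± 0.10, 0.07 ± 0.06 and -0.05 ± 0.21 and did not pass, Phex with detection on 2 of 4 arrays at 6 h. The adjusted p of the list was 0.0361, and adjusted p = 0.233 with an estimated correlation. Without DMSO array 1 it was 0.0676, with median scaling 0.0505 and without normalization between arrays 0.0901, so this call was lost in each of those 3 settings.

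Homeobox genes fell in 13 of 15 cases at 6 h, with 1 rise (14 changed when adjusted over the list alone) and a median of -1.12, or -0.84 at the bounds. Hoxa5 fell by 1.85 ± 0.09 and Six2, a gene of skeletal and kidney progenitors, by 1.18 ± 0.07. The adjusted p was 0.0039, and adjusted p = 0.21 with an estimated correlation. It was 0.065 with only probes detected on all arrays. Of 17 genes of BMP signalling, 14 fell, 1 rose and 2 did not pass (15 changed when adjusted over the list alone), with a median of -0.53. Fst (follistatin) and Grem1 (gremlin), both secreted antagonists, had log2 changes of -3.19 ± 0.06 and -2.94 ± 0.09, the ligand gene Bmp4 fell by 0.92 ± 0.05, and Id1, a target of the pathway, was the member that rose (2.35 ± 0.08). In camera the BMP list had an adjusted p of 0.00817, and adjusted p = 0.233 with an estimated correlation. Tgfb1 fell by 0.72 ± 0.13 and Pik3r1 rose by 0.59 ± 0.08.

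Cell cycle genes of G2 and mitosis fell in 18 of 22 cases at 6 h, rose in 1 and did not pass in 3 (19 changed when adjusted over the list alone), with a median of -0.78. Cdc20 fell by 2.26 ± 0.06, Plk1 by 2.05 ± 0.09 and Aurka by 1.59 ± 0.06. These mitotic genes had a list adjusted p of 0.000277, and adjusted p = 0.21 with an estimated correlation. In the list of G1, S phase and replication genes, 9 of 30 rose and 13 fell (21 changed when adjusted over the list alone, adjusted p = 0.506 in camera). Tk1 (thymidine kinase) fell by 2.41 ± 0.06 and Ccnd1 by 1.78 ± 0.06. Myc was below detection after 6 h and at least 1.52-fold lower than in DMSO, Fos was higher by 1.27 ± 0.19, and Cdkn1a had a log2 change of -0.13 ± 0.06 and did not pass, though it did without array 1 (adjusted p = 0.0479) or array 12 (adjusted p = 0.0482). Replication-dependent histone genes rose in 23 of 32 cases and fell in 0 (23 changed when adjusted over the list alone), with a median of 0.68. H3c10 rose by 1.73 ± 0.06, with a log2 change of 0.92 for its other probe, and H3c13 rose by 1.61 ± 0.09. This histone list had an adjusted p of 0.000277, and adjusted p = 0.349 with an estimated correlation. Linker and variant histone genes rose in 15 of 18 cases and fell in 2 (17 changed when adjusted over the list alone), with a median of 1.02, or 0.94 at the bounds. H1f2 rose by 2.55 ± 0.08 and H1f10 by 2.02 ± 0.09, while Cenpa, the centromeric H3 variant, fell by 1.62 ± 0.07. The adjusted p was 0.0039, and adjusted p = 0.252 with an estimated correlation.

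Deacetylase and sirtuin genes rose in 9 of 16 cases at 6 h and fell in 5 (14 changed when adjusted over the list alone, adjusted p = 0.717 in camera). Hdac11 rose by 1.38 ± 0.10 and Hdac3 by 0.55 ± 0.05, Hdac7 fell by 2.12 ± 0.07, and Hdac2 had a log2 change of -0.05 ± 0.06 and did not pass. Of the 21 ribosomal protein genes, 1 rose, 2 fell and 18 did not pass (3 changed when adjusted over the list alone, adjusted p = 0.837 in camera). Actb and Tbp had log2 changes of 0.06 ± 0.05 and -0.12 ± 0.06 and did not pass, and Gapdh rose by 0.25 ± 0.05, while another probe of Actb had a log2 change of 0.80. Lists of other mesenchymal and blood cell types did not pass in camera at 6 h. Chondrocyte genes fell in 5 of 6 cases (5 changed when adjusted over the list alone, adjusted p = 0.099), adipocyte genes rose in 3 and fell in 2 of 6 (5, 0.619), skeletal muscle genes rose in 2 and fell in 2 of 7 (4, 0.989), and macrophage and blood genes rose in 1 and fell in 5 of 6 (6, 0.406). Comp, a cartilage matrix gene, went below detection and was at least 1.53-fold lower, Pnpla2, the adipose triglyceride lipase gene, rose by 2.27 ± 0.07, and Cd14, a monocyte receptor gene, fell by 1.63 ± 0.12 with detection on 2 of 4 arrays at 6 h.

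After 6 h, 7083 genes had changed against DMSO in limma at an adjusted p under 0.05, 3562 up and 3521 down. At least 2-fold changes were found for 1899 genes, 919 up and 980 down, or for 1740 at the bounds, and the groups did not overlap for 70.8% of genes. Camera moved 7 of 49 lists, and 0 with an estimated correlation, where 9 lists passed at an unadjusted p under 0.05, while fry moved 41. As many lists were moved in 6 of the 35 splits of these arrays, the real one included, and the others again kept part of the contrast.

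**Figure D2:**
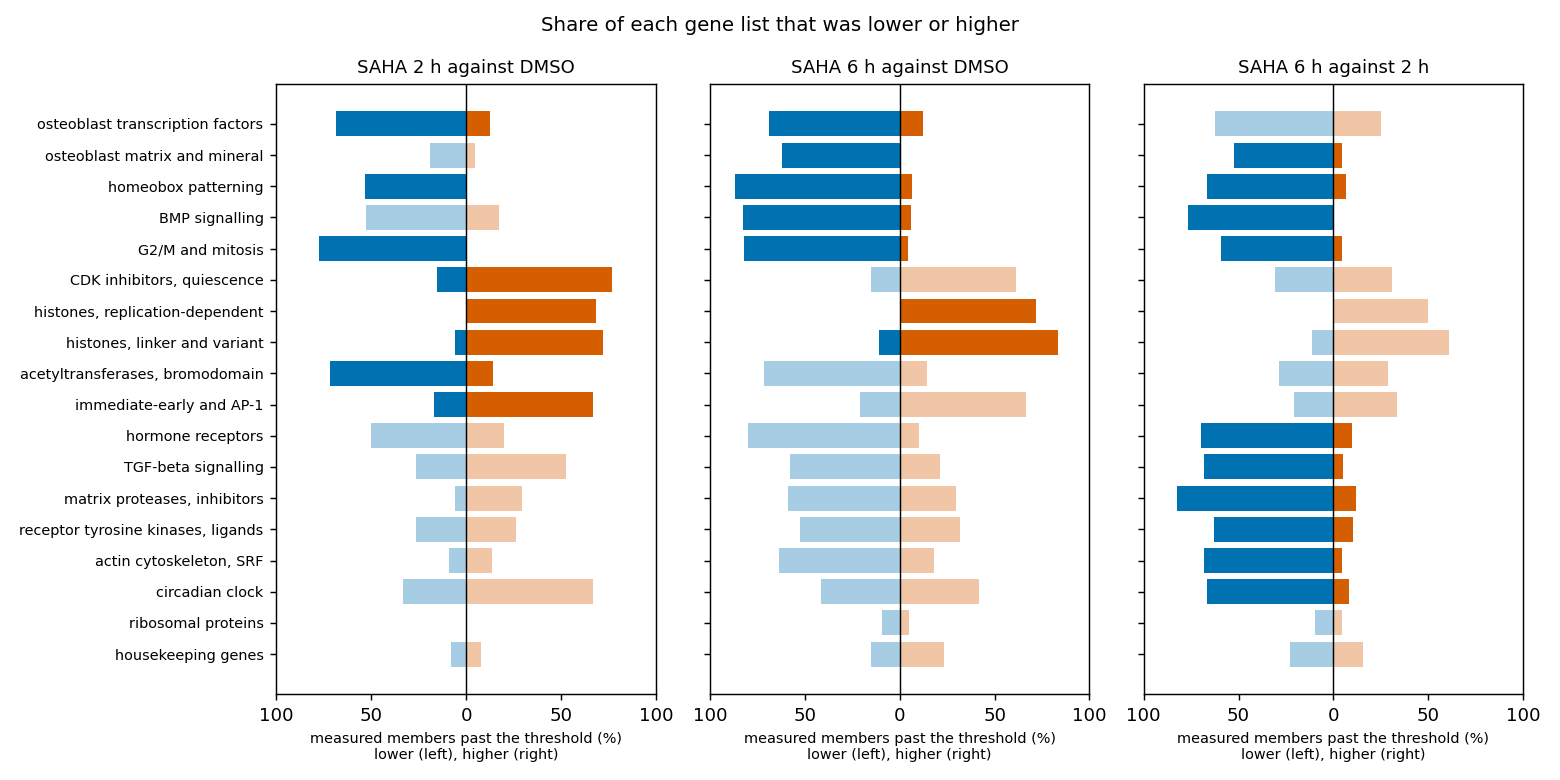
Percent of the measured members of 18 gene lists that were lower (blue, to the left) or higher (orange, to the right) at an adjusted p under 0.05 over all genes, in each of the 3 comparisons. Full colour marks lists that camera moved at the preset correlation, and none was moved with an estimated correlation. Mitotic genes stood lower in 17 of 22 cases at 2 h and in 18 of 22 at 6 h.

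The comparison of 6 h with 2 h of SAHA asked what changed between the times, and set the SAHA groups against each other in the fit of all 3 groups (5668 genes differed when the DMSO arrays were left out of the fit). Ccn5 was 11.5-fold lower at 6 h than at 2 h (-3.52 ± 0.06), Prrx1 9.53-fold lower (-3.25 ± 0.07), Scx, the transcription factor gene of tendon, 8.62-fold lower (-3.11 ± 0.08), and Panx3 8.16-fold lower (-3.03 ± 0.07). Other probes of Prrx1 had log2 changes from -3.27 to -1.67. Pth1r, the receptor gene for parathyroid hormone, was 5.70-fold lower (-2.51 ± 0.08) and Gper1 fell by 2.49 ± 0.07. Prss46, Ptprv and Lpin3 were below detection at 6 h and at least 3.52-fold, 3.09-fold and 3.04-fold lower. Reep6 rose 6.48-fold (2.70 ± 0.13), Mlf1 by 2.61 ± 0.11 and Gch1 by 2.51 ± 0.12. Among genes undetected at 2 h, Hap1 was at least 4.64-fold, Coro1a, an actin-binding gene of blood cells, at least 4.45-fold, Mgarp at least 3.29-fold, Lama5, a laminin gene, at least 2.49-fold, Extl1 at least 2.41-fold, Igsf9 at least 2.10-fold and Smtnl2 at least 2.07-fold higher. The chosen probe of Ackr4 fell by 4.29 ± 0.06, and its probe detected on all arrays had a log2 change of 1.08.

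All 10 lists that camera moved between the times were lower at 6 h. Genes of TGF-beta signalling fell in 13 of 19 cases and rose in 1 (14 changed when adjusted over the list alone), with a median of -0.58. The ligand gene Tgfb3 fell by 1.86 ± 0.08 and the receptor gene Tgfbr2 by 1.14 ± 0.06, at an adjusted p of 0.00192 for the list, and adjusted p = 0.128 with an estimated correlation. Matrix proteases and their inhibitors fell in 14 of 17 cases and rose in 2 (17 changed when adjusted over the list alone), with a median of -0.33. Adamts4, an aggrecanase gene, fell by 1.51 ± 0.09 and Mmp14, a membrane collagenase gene, by 1.10 ± 0.07 (list adjusted p = 0.00195, and adjusted p = 0.129 with an estimated correlation). BMP genes fell in 13 of 17 cases and rose in 0 (13 changed when adjusted over the list alone), with a median of -0.32 and falls of 2.25 ± 0.09 for Grem1 and 1.60 ± 0.06 for Fst, at an adjusted p of 0.00345, and adjusted p = 0.155 with an estimated correlation. Receptor tyrosine kinases and their ligands fell in 12 of 19 cases and rose in 2 (14 changed when adjusted over the list alone), with a median of -0.46. Of the PDGF receptor genes, Pdgfrb was 2.37-fold lower and Pdgfra fell by 1.24 ± 0.05 (list adjusted p = 0.00493, and adjusted p = 0.155 with an estimated correlation). Actin and SRF target genes fell in 15 of 22 cases and rose in 1 (16 changed when adjusted over the list alone), with a median of -0.34, or -0.30 at the bounds. Tagln (transgelin) fell by 1.31 ± 0.12 and Lmna (lamin A) by 1.17 ± 0.07, at an adjusted p of 0.006 for the list, and adjusted p = 0.128 with an estimated correlation.

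Mitotic genes fell further between the times in 13 of 22 cases and rose in 1 (14 changed when adjusted over the list alone), with a median of -0.26, or -0.24 at the bounds, and a fall of 1.35 ± 0.06 for Cdc20. The adjusted p was 0.006, 0.0552 without normalization between arrays, and adjusted p = 0.166 with an estimated correlation. Osteoblast matrix genes fell in 11 of 21 cases and rose in 1 (12 changed when adjusted over the list alone), with a median of -0.35 and falls of 1.40 ± 0.13 for Omd and 0.99 ± 0.10 for Alpl, at an adjusted p of 0.006, and adjusted p = 0.129 with an estimated correlation. Homeobox genes fell in 10 of 15 cases and rose in 1 (11 changed when adjusted over the list alone), with a median of -0.32, or -0.19 at the bounds. Six2 fell by 1.15 ± 0.07 (list adjusted p = 0.006, and adjusted p = 0.129 with an estimated correlation). Hormone receptor genes fell in 7 of 10 cases and rose in 1 (8 changed when adjusted over the list alone), with a median of -0.65, or -0.58 at the bounds. After Pth1r, the estrogen receptor gene Esr1, detected on 1 of 4 arrays at 6 h, fell by 1.53 ± 0.14, while Vdr, the vitamin D receptor gene, rose by 0.57 ± 0.06. For the hormone receptor list it was an adjusted p of 0.0319, 0.24 with only probes detected on all arrays, and adjusted p = 0.155 with an estimated correlation. Circadian clock genes fell in 8 of 12 cases and rose in 1 (9 changed when adjusted over the list alone), with a median of -0.39. Bhlhe40, a clock repressor gene, fell by 0.99 ± 0.08 and Per2 by 0.79 ± 0.08. The adjusted p was 0.0319, 0.0505 with only probes detected on all arrays, 0.0565 without normalization between arrays, and adjusted p = 0.155 with an estimated correlation.

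Between the times 5743 genes differed in limma at an adjusted p under 0.05, 3145 higher and 2598 lower at 6 h. At least 2-fold differences were found for 639 genes, 250 higher and 389 lower, or for 559 at the bounds, and 55.4% of genes had groups without overlap. Camera moved 10 of 49 lists, and 0 with an estimated correlation, where 12 lists passed at an unadjusted p under 0.05, while fry moved 40. As many lists were moved in 7 of the 35 splits of these arrays, the real one included, and the others again kept part of the contrast. Without normalization between arrays, 3470 genes changed at 2 h and 3517 between the times, where the median log2 change of all genes lay at 0.19 and -0.20, and the balance turned among genes changed at least 2-fold at 2 h (492 up, 224 down) and widened between the times (137 higher, 670 lower). In that setting the calls at 2 h of Prrx1, Phospho1, Ccnd1 and Hdac7 were lost, as was the rise of Vdr between the times and that of Gapdh at 6 h.

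The overlap of the time points asked whether the changes at 2 h were held at 6 h. Sp7, Fgf7 and Prrx1 fell at both times and more at 6 h, Pkp2 rose at both, and Trib3 fell by 3.55 ± 0.07 at 2 h and by 1.88 ± 0.07 at 6 h. Between the times Trib3 rose by 1.67 ± 0.07 by this probe, against 0.36 to 0.49 by its other 2 probes, so the size of the return depends on the probe. Kmt5b fell at both times, by 3.21 ± 0.08 at 6 h. Tgfb3 rose by 0.32 ± 0.08 at 2 h and fell by 1.54 ± 0.08 at 6 h, and Csf1, the macrophage colony-stimulating factor gene, rose by 0.35 ± 0.09 and then fell by 1.79 ± 0.09. In all, 4538 genes changed the same way at both times, 2246 up and 2292 down, where lists of these sizes drawn independently would share 992 and 1081. Opposite changes were found for 208 genes, of which 73 rose and then fell. Of the 8667 genes detected on at least 1 array of each group, 4225 changed the same way and 199 in opposite directions. Of the genes changed the same way, 2600 had a larger change at 6 h and 415 a smaller one, by the limma test between the times. Of the 614 genes that passed only at 2 h, 452 differed between the times. Across genes, which are not independent replicates, the log2 changes at the 2 times had r = 0.79, where unchanged groups set against the shared DMSO arrays gave 0.47 to 0.52 in 100 simulations. The covariance of these log2 changes was 0.357, against a mean of 0.0043 in the simulations. With separate DMSO arrays for each time, the 6 possible splits gave r from 0.761 to 0.784 and 3825 to 3998 shared genes.

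**Figure D3:**
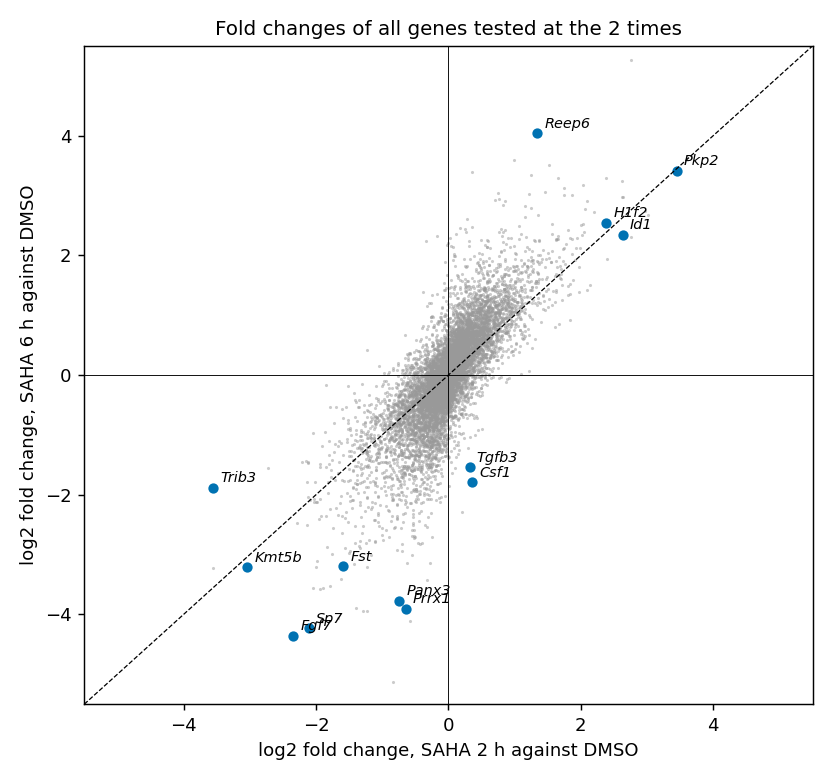
Log2 fold change of each of the 9153 genes after 6 h of SAHA (vertical axis) against that after 2 h (horizontal axis), both against DMSO, with named genes in blue and a dashed line where both are equal. Sp7, Fgf7 and Prrx1 lie below the dashed line, and Tgfb3 and Csf1 lie to the right of 0 and below it. Values of genes undetected in a group are fitted values.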

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

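The splits of the arrays and the test of brightness for the least bright matrix gene were planned, while the tests of the 3 brightest matrix genes, of the share of osteoblasts and of array scaling were chosen only after the result was seen. For the counts of changed genes, 1 of 35 splits, the real one, reached the 5360, 7083 and 5743 genes of the 3 comparisons. The highest other count was 1, 0 and 0. The same holds for the 633, 1899 and 639 genes changed at least 2-fold, reached by 1 of 35 splits, with 0 in all others. Every other split mixes the groups, so the difference between them enters the spread and low counts were fixed in advance. The splits thus single out the real grouping but cannot exclude chance as the source. For the number of moved lists, the splits cannot decide on chance as the source. At 2 h, 2 of 35 splits moved at least 8 lists and the highest other count was 9. At 6 h 6 splits moved at least 7 with a highest other count of 9, and between the times 7 splits moved at least 10 with a highest other count of 12. All of these besides the real one exchanged 1 array of each group, so they kept part of the contrast. Splits with 2 arrays of each group on both sides moved at most 1, 2 and 3 lists, but they mix the groups in the spread.

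Of 16 osteoblast regulators 11 fell at 6 h, 2 rose and 3 did not pass, with a median log2 change of -0.77, or -0.58 at the bounds. Of 21 osteoblast matrix genes 13 fell and 8 did not pass, among them 4 of the 10 brightest. No test compared the lists. The 4 were picked because they did not pass, while the rest of the 10 fell, so no contrast by brightness within the matrix list is shown. These 4 were Ibsp (0.08 ± 0.14), Col1a1 (0.07 ± 0.06), Sparc (-0.03 ± 0.07) and Col1a2 (-0.05 ± 0.08), of which Sparc and Col1a2 were named after their values were seen. A signal too bright to fall is argued against for Ibsp, since 9.51% of the 1504 other genes at least as bright fell 2-fold or more, against 10.7% of all genes, but it stays open for the other 3, where 4.05% of 74 genes as bright did so. A lower share of osteoblasts as the whole cause would lower every osteoblast gene alike and is argued against by genes fixed by name, since the upper 95% limit of Sp7 was -4.07 and the lowest limit of Alpl, Ibsp, Bglap, Col1a1 and Phex was -1.35, but a lower share as part of the smaller falls stays open. Under 5 other settings, all 8 regulators that were detected on at least 1 array of both groups and fell at least 1.5-fold kept their calls. The settings were no background correction, median scaling, cyclic loess normalization, the authors' normalized values and no normalization between arrays. Of the 2 smaller falls 1 kept its call in all 5. The other was Atf4 (-0.17 ± 0.07, named after its value was seen), with adjusted p = 0.0765 to 0.115 without any 1 of arrays 3, 4, 9 and 12. Atf4 lost its call at -0.11 ± 0.08 with median scaling and at -0.19 ± 0.18 with no normalization between arrays. In the latter setting the fold was kept and the error grew, so scaling of the arrays is neither shown nor excluded for Atf4. An effect of SAHA on the larger falls may remain, but time in culture was not separated from SAHA.

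The times differed for 5743 genes by the limma test between 6 h and 2 h. Among the 142 genes named, 3 of those detected in each group changed in opposite directions at the 2 times. Differences between 6 h and 2 h were -2.14 for Csf1, -1.86 for Tgfb3 and -0.79 for Per2 (0.51 ± 0.08, then -0.28 ± 0.08).

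Among the 2295 kept probes without 1 gene symbol, which the comparisons did not use, 1083 changed at 2 h, 1460 at 6 h and 1030 between the times. At 6 h the probe ILMN_1246061 rose by 2.93 ± 0.07, ILMN_1255621 rose by 2.67 ± 0.13, ILMN_1254827 had a log2 change of -4.21 ± 0.08 and ILMN_2626190 of -3.42 ± 0.09.

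A single array lay far from the other 3 of its group by Dixon's ratio of gap to range, for 21 of 426 pairs of a named gene and a group, where chance marks about 1 in 20, or 21.3. Of 15 array measures 1 was so marked, the mean intensity of DMSO array 3 (0.961 of the range), at 852 where the other 3 lay between 747 and 751. Among the 2 h arrays, array 8 stood apart for Itpka (0.959), Mcam (0.888), Adamts4 (0.887), H2ac6 (0.846) and Mmp14 (0.846). Array 5 did so for Id1 (0.915), Panx3 (0.895) and Pkp2 (0.854), array 6 for Apaf1 (0.885) and H3c13 (0.875), and array 7 for Bmf (0.901). In DMSO, array 4 stood apart for Omd (0.976), Lmna (0.929), Syn1 (0.913) and Extl1 (0.841), and array 2 for Nkd2 (0.888). In the 6 h group this was array 10 for Gapdh (1, after rounding) and Lama5 (0.914), array 12 for Fosl2 (0.894), and array 9 for Tnfrsf11b (0.848) and Dlx3 (0.832).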

How the results depend on the processing

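The absence of normalization between arrays and the replicate block on the authors' normalized values were chosen after seeing the data, and all other alternatives were planned. Signal over background limits the folds of dim genes, and no slide is given for the arrays, so a slide block was not run. Replicate numbers were not taken to pair samples, since same-number pairs correlated over 0.1 in 10 of 12 cases and not in all. Their r ran from -0.036 to 0.356, against -0.367 to 0.293 for the 36 other pairs. Besides, 5 of 12 samples correlated best with their own number in both other groups, a hint of pairing from the data. Pairing thus stays open, and the main fit would ignore it. With the block, 5877, 7301 and 6148 genes changed, against 5506, 7106 and 5836 on the same values without it. Of 366 calls for the 142 named genes, 308 kept call and direction in all settings run, up to 24 for a gene, and 54 were lost in at least 1 of them, while of 60 results of named genes that did not pass 34 passed in at least 1. Of 122 lists not moved 19 moved in at least 1 setting, none of the 25 moved lists turned direction, and 7 lost their call in a setting other than an array left out or an estimated correlation. Leaving out each array in turn gave 4975 to 5417 changed genes at 2 h, 6882 to 7119 at 6 h and 5403 to 5755 between the times. Genes changed at least 2-fold numbered 623 to 654, 1878 to 1913 and 628 to 663, moved lists 8 to 8, 6 to 8 and 10 to 11, shared genes 4269 to 4547, and r lay between 0.782 and 0.792.

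Without background correction, 375 genes at 2 h and 367 between the times changed at least 2-fold, where background left in the values shrinks folds. On the authors' normalized values with or without the replicate block these were 359 and 357. The medians of those values, 98.1 to 99.15, lay near those of the intensities before background correction (93.2 to 110). Background left in could thus shrink these folds too, but this was not tested. Without a probe filter 12 lists moved at 6 h and 17 between the times, and the cause was not tested. Without normalization between arrays, 3470 genes changed at 2 h (72.9% of them higher, against 47.6%) and 3517 between the times (20.6% higher, against 54.8%), with 2750 shared. There the brightness of the 2 h arrays enters the changes, and of the calls for named genes 98 of 118, 127 of 130 and 93 of 118 were kept. Camera with an estimated correlation moved 0, 0 and 0 lists, with adjusted p from 0.128 to 0.361 for the 25 lists moved before, and fry, which tests another hypothesis, moved 28, 41 and 40. Split controls gave r = 0.773, 0.769, 0.768, 0.761 and 0.768 in 5 of 6 splits, with fewer control arrays in each comparison and none shared. With probes detected on all arrays, Ackr4 turned to 0.47, 1.56 and 1.08, since another of its probes was used. With the mean of probes Hdac2 turned to 0.18 at 2 h. With no normalization between arrays, Hdac2 and Ogn at 2 h turned to 0.079 and 0.052 and Gapdh between the times to -0.029. All other alternatives kept the counts within 1.5 times.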

Other observations

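The tests of zinc finger genes and of genes coming on or off were written down before their results were seen. Neither was among the comparisons planned before the data were examined. Zfp551 was among the 10 largest falls at 2 h, so these same data may have prompted the zinc finger test. The check of the zinc finger genes under other settings and that of the number of detected probes were added only after the result was seen. In the Wnt list, 7 of 25 measured genes rose and 9 fell at 6 h (16 changed when adjusted over the list alone, adjusted p = 0.539 in camera). Nkd2 and Axin2, both feedback inhibitors, fell by 3.21 ± 0.09 and 1.15 ± 0.06, Nkd2 with detection on 1 of 4 arrays at 6 h, and the ligand gene Wnt10a fell by 2.80 ± 0.09, while the ligand gene Wnt4 rose by 1.92 ± 0.08. In the Notch list, 7 of 11 rose and 3 fell (10 changed when adjusted over the list alone, adjusted p = 0.278), with Notch1 up by 1.97 ± 0.09 and the target genes Hey1 and Hes1 up by 1.91 ± 0.12 and 1.42 ± 0.09, Hey1 with detection on 1 of 4 DMSO arrays. Of 8 genes of osteoclast coupling and cytokines, 3 rose and 5 fell (8 changed when adjusted over the list alone, adjusted p = 0.278). Tnfrsf11b, which encodes osteoprotegerin, had a log2 change of -3.52 ± 0.13 and Sema3a (semaphorin 3A) of -2.82 ± 0.09. The other probe of Sema3a had a log2 change of -1.50.

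Of 8 measured neuronal genes, 4 rose and 2 fell at 6 h (6 changed when adjusted over the list alone, adjusted p = 0.493). Map2, Rab3a and Syn1, genes of dendrites and synaptic vesicles, rose by 2.03 ± 0.08, 2.01 ± 0.09 and 1.85 ± 0.06, and Syt4 (synaptotagmin 4) fell by 1.96 ± 0.11. In the list of endoplasmic reticulum and integrated stress, 9 of 25 genes rose and 7 fell at 2 h (17 changed when adjusted over the list alone, adjusted p = 0.867). Herpud1 and Chac1 fell by 2.02 ± 0.06 and 1.84 ± 0.09, and Chac1 rose by 1.68 ± 0.09 between 2 h and 6 h. Genes of the BCL2 family and apoptosis rose in 8 of 17 cases and fell in 6 at 2 h (15 changed when adjusted over the list alone, adjusted p = 0.756). The median of that list was -0.11 and its mean 0.19. Bmf and Apaf1, which promote apoptosis, rose by 1.16 ± 0.09 and 0.94 ± 0.07, and Bcl2l2, which opposes it, fell by 0.93 ± 0.05 by the probe used, while another of its 3 probes had a log2 change of 0.63. Circadian genes rose in 8 of 12 cases and fell in 4 at 2 h (12 changed when adjusted over the list alone, adjusted p = 0.159), with Cry2 up by 1.81 ± 0.09 and Per1 by 1.08 ± 0.06. Immediate-early genes at 6 h rose in 16 of 24 cases and fell in 5 (21 changed when adjusted over the list alone, adjusted p = 0.0659), with Atf3 up by 2.30 ± 0.13 and Egr1 by 2.09 ± 0.12. Acetyltransferase and bromodomain genes at 6 h fell in 10 of 14 cases and rose in 2 (12 changed when adjusted over the list alone, adjusted p = 0.099), with falls of 1.44 ± 0.11 for Ep300 and 1.30 ± 0.05 for Brd9. CDK inhibitors and quiescence genes at 6 h rose in 8 of 13 cases and fell in 2 (10 changed when adjusted over the list alone, adjusted p = 0.278).

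A hypothesis held that genes named as zinc finger proteins, by Zfp and a number, fell at 2 h more often than others. Of 184 such genes, 108 fell (58.7%, exact 95% interval 51.2 to 65.9) and 26 rose, against 30.1% of 8969 other genes that fell (Fisher's exact test, two-sided, odds ratio 3.29, p = 2.55e-15, with genes that are not independent). Dim probes are argued against, since genes of the same brightness would give 31.8%. The odds ratio was 3.07 to 5.04 under 5 other settings of background correction, scaling or normalization, with 35.3% against 9.77% without normalization between arrays. At 6 h 51.1% fell against 38.2% of other genes. Of the 184, 65 (35.3%) were higher at 6 h than at 2 h, against 34.3% of other genes. Lower at 6 h than at 2 h were 28 of the 184, a smaller share than the 2598 of all 9153 genes tested.

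Another hypothesis, that more genes came on than went off by 6 h, was not borne out. Detected on 0 DMSO arrays and on all 6 h arrays were 159 genes, and 200 went the other way (exact binomial test, two-sided, p = 0.0346, with genes that are not independent). At 2 h the counts were 50 and 78. More detected probes on the 6 h arrays are argued against as a source of genes coming on, since the highest number was 15705 there and 16065 in DMSO, but the lower numbers at 6 h go with more genes going off.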
